A study of Mus musculus with 12 samples.

How the data were processed

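RNA was measured by sequencing in 12 libraries of mouse bone marrow-derived macrophages, 3 for each combination of oxygen (normoxia or 1%) and 25 mM sodium lactate or NaCl. Per the labels' protocols, polyadenylated RNA was captured on oligo(dT) beads, libraries were made with an Ion Total RNA-Seq kit and read on an Ion Proton instrument. The authors deposited raw counts of reads per Ensembl gene, 1 column per library, and the submitters' processing notes name BWA, HTSeq and the mm9 genome build without versions. The annotation release and the strand setting of the counting are not given in the sources used here, so overlapping and antisense genes, near-identical copies and genes with processed pseudogenes are uncertain. The counts cover 37620 gene identifiers. A further 5 counters name no gene and were kept out of library sizes and tests. Over the libraries they held 8.34% to 18.4% (not uniquely aligned), 0.361% to 0.443% (ambiguous), 13.7% to 22.0% (outside genes), 2.02% to 5.49% (not aligned) and 0% (low quality) of all reads. Symbols were matched by identifier to a GENCODE annotation of another build, GRCm38, from which no coordinates were used: 32897 identifiers had a symbol and 4723 had none, and 14122 of the 14616 tested genes had one. Of 518 names on the gene lists, 5 had no identifier.

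Groups and library numbers were taken from the sample labels. Each of 6 comparisons was tested in 1 fit over all 12 libraries with a mean per group, using edgeR 4.0.16 (quasi-likelihood F test, TMM scaling, genes kept by filterByExpr) in R 4.3.3, with Benjamini-Hochberg adjustment over the tested genes and a threshold of 0.05. The comparisons were hypoxia without lactate (hypoxia-NaCl against normoxia-NaCl), hypoxia with lactate (hypoxia-lactate against normoxia-lactate), lactate in normoxia, lactate in hypoxia, both together (hypoxia-lactate against normoxia-NaCl) and the interaction. CPM values are TMM-scaled, except those of Arg1, Xist and the Y-linked genes, which are counts over the plain library totals, and group values are means with the SD over 3 libraries. Standard errors of edgeR's log2 fold changes were computed back from the same fit, as the absolute log2 fold change over the square root of its F statistic.

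The 28 gene lists cover glycolysis and glucose uptake, other HIF targets, alternative and pro-inflammatory activation, interferon-stimulated genes, MHC class II, cholesterol synthesis, LXR targets, nuclear-encoded and mitochondrially encoded oxidative phosphorylation, the tricarboxylic acid cycle, lactate transport, cell cycle, ATF4 response, endoplasmic reticulum chaperones, NRF2 genes, matrix and vascular factors, lysosome, macrophage identity, immediate early genes, histones, and markers of neutrophils, fibroblasts, lymphocytes, dendritic cells, mast cells, erythroid cells and osteoclasts. The 27 lists with at least 3 tested genes were tested with camera (limma 3.58.1) on voom values with a preset correlation of 0.01, and again with an estimated correlation. With the estimated correlation 1 of 12 calls held for hypoxia without lactate and 1 of 7 for hypoxia with lactate, in each case other HIF targets, and 0 in the other 4 comparisons. Those that held only with the library number as a block in the same fit are given beside their results. The count of members "adjusted over the list alone" applies the Benjamini-Hochberg method within the list.

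The groups, tests, gene lists, first set of alternatives and the rule for naming genes were fixed before the data were examined. The rule names, among genes past the threshold with at least 5 CPM on average and no overlap of the libraries compared, the 8 largest rises and 8 largest falls for hypoxia without lactate, lactate in normoxia, both together and the interaction, and the 3 largest each way for the other comparisons, skipping clone, predicted-gene and pseudogene names. It adds up to 2 risen and 2 fallen members of each list and Arg1, Mrc1, Vegfa, Nos2, Slc2a1 and Hif1a, and the text leaves out some for length. Genes named outside it are said to have been chosen after their values were seen.

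The alternatives were RLE and upper-quartile size factors, no filter, a filter at a mean of 5 CPM, DESeq2 1.42.0, limma-voom, the library number as a block, a fit of only the groups compared, and leaving out each library in turn. Chosen after seeing the data were leaving out hypoxia-lactate 3 and normoxia-NaCl 1 together, limma-voom with library quality weights, and the block with hypoxia-lactate 3 left out. The labels number libraries 1 to 3 in each group. For hypoxia without lactate the deviations of same-numbered libraries from their group means correlated at 0.138 to 0.315, all above the 0.1 set as the limit, so the numbers were taken to pair the libraries in that comparison. In the other comparisons of 2 groups the lowest such correlation was -0.069 to 0.082. Results with the block there rest on a pairing that missed this limit. The main fit does not use this pairing, which enters only the tests with the library number as a block and the splits of libraries. The pairing comes from these values and not from the labels. Libraries of a group differed by more than counting error (chi-square per degree of freedom 39.1 to 335), so all were kept as separate samples. On simulated counts with 100 changed genes of each size, the test for hypoxia without lactate recovered 13% of 2-fold and 74% of 4-fold changes with 3 false calls among 14419 genes tested. Without hypoxia-lactate 3 it recovered 68% and 99% with 8 false calls among 14814. In all these simulations the changed genes averaged at least 100 counts per library, so recovery of lower genes is not covered. Every library of a gene had the same simulated spread.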

Results

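Transcript levels were measured in primary macrophages grown from C57BL/6 mouse bone marrow and taken at day 7 of culture. The cells were kept in ordinary oxygen (normoxia) or in 1% oxygen (hypoxia), and in medium with 25 mM sodium lactate or 25 mM NaCl, the salt control. The 12 libraries form 4 groups of 3: normoxia-NaCl, normoxia-lactate, hypoxia-NaCl and hypoxia-lactate, and each library is named by its group and number. The design asks how low oxygen and lactate, conditions of poorly perfused tumour regions, act on macrophage expression alone and together. Between 22705978 and 49885085 reads per library were assigned to genes, and 14616 genes entered the tests. The labels do not say whether the 3 libraries of a group came from separate mice or cultures, so p-values measure only the spread between these samples, which may be technical. Log2 fold changes carry a standard error (SE) computed back from the F test of a fit over all 12 libraries with 3 per group. Adjusted p-values of genes come from edgeR's quasi-likelihood test with Benjamini-Hochberg (BH) adjustment, and those of gene lists from camera with BH adjustment over 27 lists.

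Library hypoxia-lactate 3 stood apart from the rest. It held 11437 genes with at least 10 counts against 13198 to 14767 in the other 11 libraries, and 0.486% of its counts were mitochondrially encoded against 2.04% to 4.75%. Its median Spearman correlation with the other libraries was 0.906, against 0.966 to 0.987 for the others. Of 8735 genes above 10 CPM (counts scaled to the library size) on average elsewhere, 244 were more than 10-fold lower in it and 98 more than 4-fold higher. Library normoxia-NaCl 1 was apart on the second principal component and had 33.7% of its counts in its 100 most abundant genes and the highest mitochondrial share, 4.75%. The common coefficient of variation within groups was 38.2% with all libraries, 24.3% without hypoxia-lactate 3, and 21.2% without both. Each count of changed genes over all genes tested, except for the interaction, is therefore also given without hypoxia-lactate 3 and without both libraries, the latter an alternative chosen after seeing the data. Counts within gene lists were not repeated for each library left out in turn. Where such a count is given and moved by more than 1.5-fold without hypoxia-lactate 3, its value without that library is given too, and genes named only from those counts were chosen after their values were seen.

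**Figure D1:**
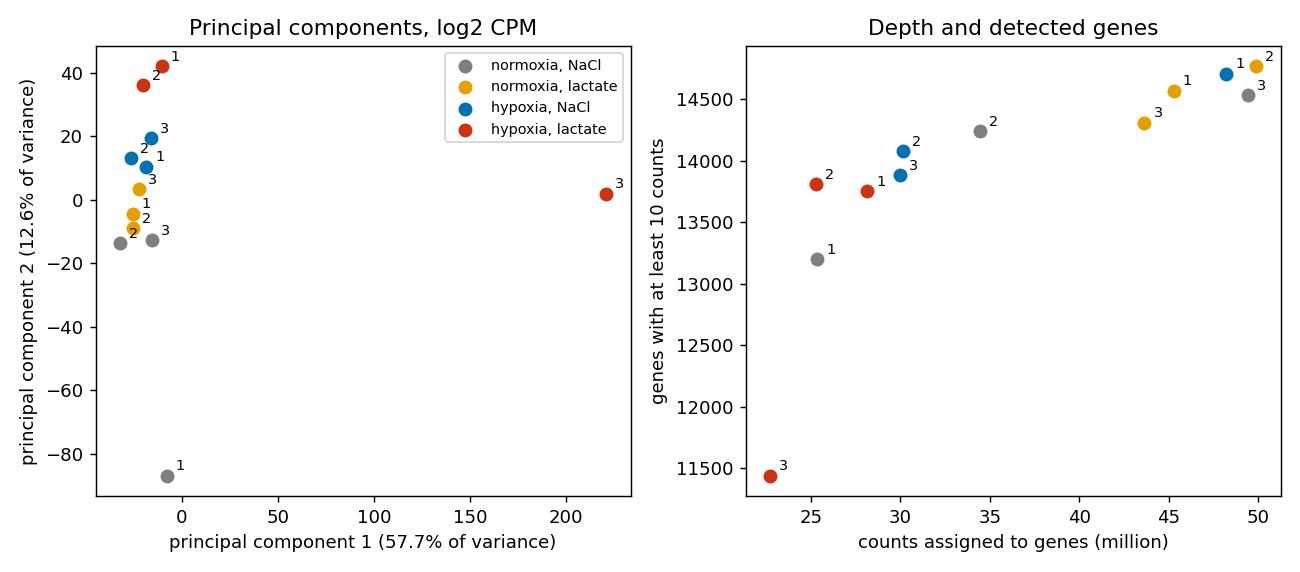
Left, principal components 1 (57.7% of variance) and 2 (12.6%) of log2 CPM, 1 point per library coloured by group; right, counts assigned to genes against the number of genes with at least 10 counts. Hypoxia-lactate 3 lies alone on the first component with 11437 detected genes, and normoxia-NaCl 1 lies alone on the second.

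Low oxygen without lactate raised targets of hypoxia-inducible factor (HIF), the transcription factor that is stabilised at low oxygen. Egln3 (ENSMUSG00000035105), a HIF prolyl hydroxylase, went from 3.66 ± 0.673 CPM (SD, n = 3) in normoxia-NaCl to 110 ± 16.2 CPM (n = 3) in hypoxia-NaCl, a log2 fold change of 4.91 ± 0.25 (SE). Ak4 (ENSMUSG00000028527), a mitochondrial adenylate kinase, rose by 4.70 ± 0.54 and Ankrd37 (ENSMUSG00000050914) by 4.68 ± 0.30. Bnip3, a mitophagy receptor, rose by 2.49 ± 0.36, Pdk1, a kinase that inhibits pyruvate dehydrogenase, by 2.34 ± 0.24, Slc16a3, a lactate exporter, by 2.27 ± 0.38, and P4ha1, a collagen prolyl hydroxylase subunit, by 2.17 ± 0.21. Hspa1b, an inducible HSP70 chaperone, rose by 2.32 ± 0.33, and the angiogenic factor Vegfa (ENSMUSG00000023951) by 2.02 ± 0.37. The genes that fell were Lrrc27 (-1.27 ± 0.19) and Csrp1 (-0.97 ± 0.17), a LIM-domain protein. In all, 39 genes were higher and 2 lower, 35 of these 41 by at least 2-fold, with edgeR BH-adjusted p from 1.28e-06 for Egln3 to 0.0421 for Vegfa among the named genes. Without hypoxia-lactate 3, which is in neither group but enters the shared spread, 186 were higher and 84 lower, and all 41 remained. Without both outlying libraries 151 were higher and 37 lower. With quality weights 316 were higher and 209 lower, and with the block without hypoxia-lactate 3 372 and 395. The share of higher genes was then 60.2% and 48.5%, against 95.1% in the main fit. With the library number as a block, 39 and 2 were called, 31 of them shared with the 41, and Slc16a3 was not (edgeR BH-adjusted p = 0.0528; 1.34e-05 to 0.192 over its alternatives).

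Among 24 other HIF targets, 9 rose and none fell, 14 and none adjusted over the list alone, with a median log2 change of 1.5 (camera adjusted p = 4.1e-28; adjusted p = 0.0303 with an estimated correlation, and 0.112 without hypoxia-lactate 3). Of 23 genes of glycolysis and glucose uptake 7 rose, 11 adjusted over the list alone, and none fell in either count, with a median of 0.89 (camera adjusted p = 3.71e-19; adjusted p = 0.0783 with an estimated correlation). They included Pgam1, phosphoglycerate mutase (1.55 ± 0.18, edgeR BH-adjusted p = 0.00261), and the glucose transporter Slc2a1 (ENSMUSG00000028645; 1.90 ± 0.26, edgeR BH-adjusted p = 0.00967). The abundant glycolytic genes and Ak4 have processed pseudogenes, and Hspa1b is nearly identical to Hspa1a, so their counts are uncertain where reads could be split. Slc16a3 was the 1 of 8 genes of lactate transport and interconversion that rose (2 higher and 1 lower adjusted over the list alone), and Vegfa the 1 of 27 of matrix remodelling and vascular factors (2 higher adjusted over the list alone). Without hypoxia-lactate 3, 14 HIF targets and 11 glycolysis genes rose, with 17 and 14 higher and 1 lower each adjusted over the list alone. Ldha and Mmp13, a collagenase, then rose beside Slc16a3 and Vegfa in the other two lists (3 higher and 2 lower, and 2 higher, adjusted over the list alone).

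Further lists passed camera's test with the preset correlation while edgeR called no single member with all 12 libraries. All 23 cholesterol synthesis genes were lower, with a median of -0.52 (camera adjusted p = 5e-10; adjusted p = 0.0783 with an estimated correlation, and 0.00758 with the library number as a block too; 5 lower at an unadjusted p under 0.05, 1 by DESeq2, 0 by limma-voom, 0 adjusted over the list alone). All 31 nuclear-encoded genes of oxidative phosphorylation were lower, with a median of -0.41 (camera adjusted p = 2.38e-08; adjusted p = 0.226 with an estimated correlation; 5 lower at an unadjusted p under 0.05, 0 by DESeq2 and limma-voom, 0 adjusted over the list alone). Without normoxia-NaCl 1 that median was -0.18. The lysosome list (24 genes, median -0.33, camera adjusted p = 0.000153) and the tricarboxylic acid cycle list (24 genes, -0.32, 1 lower adjusted over the list alone, camera adjusted p = 0.000964) were lower, with adjusted p = 0.265 and adjusted p = 0.226 with an estimated correlation. The lysosome median was -0.15 without normoxia-NaCl 1. The NRF2 antioxidant list was lower (14 genes, -0.28, 2 lower adjusted over the list alone, camera adjusted p = 0.00177; adjusted p = 0.226 with an estimated correlation). Cell cycle genes had 29 of 30 members lower and a median of -0.48 (camera adjusted p = 2.07e-06; adjusted p = 0.323 with an estimated correlation). Without normoxia-NaCl 2 the median was -0.21 and the camera adjusted p 0.101. Without hypoxia-lactate 3 edgeR called the cholesterol genes Mvk and Fdps, the tricarboxylic acid cycle gene Idh2 and the NRF2 genes G6pdx and Osgin1, all lower. Adjusted over the list alone, 13 cholesterol, 8 tricarboxylic acid cycle, 4 NRF2, 3 lysosome and 1 cell cycle genes were then lower and 1 tricarboxylic acid cycle gene higher. The 13 mitochondrially encoded genes also passed as a list without that library (median -0.38, camera adjusted p = 0.0203, against 0.117; adjusted p = 0.69 with an estimated correlation) and not without both outlying libraries (0.15, 0.193).

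Interferon-stimulated genes (26 genes, median -0.31, camera adjusted p = 0.00219) and ATF4 amino acid response genes (22 genes, -0.45, camera adjusted p = 0.00163) were lower too, with adjusted p = 0.226 and adjusted p = 0.323 with an estimated correlation. The first passed no longer without normoxia-NaCl 2 (-0.19, 0.117) and the second without hypoxia-NaCl 3 (-0.30, 0.0782). The pro-inflammatory list was higher (21 genes, median 0.34, 3 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.0154; adjusted p = 0.323 with an estimated correlation). It did not pass without hypoxia-NaCl 1 (0.23, 0.198) or normoxia-NaCl 3 (0.22, 0.192). The 3 tested histone genes had a median of 0.93 (camera adjusted p = 0.0226; adjusted p = 0.226 with an estimated correlation) and passed without hypoxia-lactate 3 or normoxia-NaCl 1. Without any 1 of the others camera adjusted p was 0.161 to 0.853, with medians of 0.22 without hypoxia-NaCl 3 and 0.59 without normoxia-NaCl 2. Antigen presentation by MHC class II (12 genes, 11 of them positive, median 0.35) passed with the library number as a block (camera adjusted p = 0.00349; adjusted p = 0.133 with an estimated correlation) and not without it (0.148). Without both outlying libraries it was higher (0.58, 0.0248; adjusted p = 0.53 with an estimated correlation), as was lactate transport and interconversion (median 0.26, camera adjusted p = 0.0209; adjusted p = 0.352 with an estimated correlation). Without hypoxia-lactate 3 the interferon-stimulated gene Bst2 fell and the pro-inflammatory genes Il1b, Nfkbiz and Tnfaip3 rose. Adjusted over the list alone, 3 interferon-stimulated genes were then lower, 8 ATF4 genes lower and 1 higher, 5 pro-inflammatory genes higher and 2 lower, and 3 histone genes higher.

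Of the single-gene calls, those of Egln3, Ak4, Ankrd37, P4ha1, Pdk1 and Pgam1 held in all 23 alternatives. The edgeR BH-adjusted p of Bnip3 was 0.0919 without normoxia-NaCl 2 and 0.118 without normoxia-NaCl 3, over a range of 4.11e-08 to 0.118. Without normoxia-NaCl 1, 2 and 3 in turn it was 0.11, 0.0584 and 0.104 for Hspa1b (5.07e-08 to 0.11 over all alternatives) and 0.0864, 0.0702 and 0.0772 for Slc2a1 (1.81e-07 to 0.0864). Lrrc27 lost its call without hypoxia-NaCl 1, 2 or 3 (0.12, 0.095, 0.0959) or normoxia-NaCl 1 or 3 (0.0864, 0.109), over a range of 2.14e-09 to 0.12. Slc16a3 lost it without hypoxia-NaCl 1, 2 or 3 (0.111, 0.0555, 0.131), normoxia-NaCl 1, 2 or 3 (0.145, 0.161, 0.192) or normoxia-lactate 1 (0.0618). Vegfa lost it with another scaling of library sizes (0.0755, RLE size factors) and without hypoxia-NaCl 1, 2 or 3 (0.126, 0.166, 0.169), normoxia-NaCl 1, 2 or 3 (0.314, 0.208, 0.192) or normoxia-lactate 1, 2 or 3 (0.089, 0.055, 0.0527), over a range of 1.34e-05 to 0.314. Csrp1 lost it with upper-quartile factors (0.0863), with no filter (0.0649), and without each of hypoxia-NaCl 1, 2 and 3 (0.226, 0.173, 0.169), normoxia-NaCl 1, 2 and 3 (0.132, 0.139, 0.115), and normoxia-lactate 1 and 2 (0.0774, 0.056), over a range of 5.08e-08 to 0.226. The total of 41 changed genes moved by more than 1.5-fold without hypoxia-NaCl 1, 2 or 3 (19, 19, 14), normoxia-NaCl 1, 2 or 3 (9, 13, 7), normoxia-lactate 1 (19) or hypoxia-lactate 3 (270).

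Low oxygen in the presence of lactate raised the same leading genes. Ankrd37 rose by 4.53 ± 0.30, Egln3 by 4.38 ± 0.25 and Ak4 by 3.59 ± 0.51 on the log2 scale. Slc16a3 rose by 2.76 ± 0.39, Vegfa by 2.47 ± 0.37, Pdk1 by 2.1 ± 0.24, the glycolytic regulator Pfkfb3 by 1.93 ± 0.24 and Slc2a1 by 1.92 ± 0.26. Over the alternatives the rise was 2.119 to 3.067 for Slc16a3 and 1.823 to 2.711 for Vegfa. Ldha, lactate dehydrogenase A, rose by 1.77 ± 0.30, the cysteine protease Ctsk by 1.74 ± 0.31 and the fractalkine receptor Cx3cr1 by 1.58 ± 0.28, while Lgals9, which encodes galectin-9, fell from 27.0 ± 5.14 CPM (SD, n = 3) to 9.75 ± 2.73 CPM (n = 3), a log2 change of -1.47 ± 0.26. In all 29 genes were higher and 4 lower, all 33 by at least 2-fold, with edgeR BH-adjusted p from 3.49e-06 for Egln3 to 0.0457 for Ctsk among the named genes. Of the 39 genes higher without lactate and the 29 higher with it, 20 were shared, where independent lists would share 0.0774. The lower lists of 2 and 4 genes shared none, with 0.000547 for independent lists. Without hypoxia-lactate 3, 98 were higher and 32 lower and all 33 calls remained. Without both outlying libraries 236 were higher and 144 lower, and with the library number as a block 32 and 2, 25 of them shared with the 33. The total of 33 also moved by more than 1.5-fold without hypoxia-NaCl 1 or 2 (21 each), hypoxia-lactate 2 (50), or normoxia-lactate 1, 2 or 3 (3, 12, 8).

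Of the 24 other HIF targets 10 rose with lactate present, 18 adjusted over the list alone, with a median of 1.84 (camera adjusted p = 2.99e-27; adjusted p = 0.00162 with an estimated correlation). Of 23 glycolysis genes 10 rose, 17 adjusted over the list alone, with a median of 1.23 (camera adjusted p = 1.01e-23; adjusted p = 0.0506 with an estimated correlation, and 0.0491 with the library number as a block too). Same-numbered libraries correlated at 0.023 to 0.126 here, so the block rests on a pairing that missed the limit of 0.1. The HIF and glycolysis medians were 1.556 and 1.155 without hypoxia-lactate 3, against 1.496 and 0.887 for low oxygen without lactate in that fit. Slc16a3 and Ldha were the 2 of 8 lactate transport and interconversion genes that rose (3 higher and 1 lower adjusted over the list alone). Endoplasmic reticulum chaperones were higher as a list (14 of 17 positive, median 0.24, camera adjusted p = 0.000431; adjusted p = 0.328 with an estimated correlation; median 0.38 without hypoxia-lactate 1). Interferon-stimulated genes were lower (19 of 26 negative, median -0.51, camera adjusted p = 0.00136; adjusted p = 0.328 with an estimated correlation). The pro-inflammatory list was higher (4 of 21 adjusted over the list alone, median 0.51, camera adjusted p = 0.0135; adjusted p = 0.509 with an estimated correlation). It was at 0.0631 without hypoxia-lactate 1 and 0.131 without hypoxia-lactate 2, and with a median of 0.31 without hypoxia-lactate 3. Cholesterol synthesis was lower (median -0.50, camera adjusted p = 0.00608; adjusted p = 0.406 with an estimated correlation, and 0.0491 with the block too), at 0.15 without hypoxia-lactate 1 and 0.0524 without normoxia-lactate 2. The 13 mitochondrially encoded genes had a median of -0.64 (camera adjusted p = 0.00827; adjusted p = 0.816 with an estimated correlation). That median was -0.09 (0.563) without hypoxia-lactate 3, the library with 0.486% mitochondrial counts, and camera adjusted p was 0.094 without normoxia-lactate 3. Nuclear-encoded oxidative phosphorylation was lower without both outlying libraries (median -0.15, camera adjusted p = 0.00313; adjusted p = 0.497 with an estimated correlation). Without hypoxia-lactate 3 the ATF4 list was higher (median 0.32, camera adjusted p = 0.034) and the lysosome list lower (-0.26, 0.0127), both at 0.269 with all libraries and each with adjusted p = 0.631 with an estimated correlation. Il1b, Nos2 and Tnfaip3 then rose and Bst2 fell, with 7 pro-inflammatory genes higher and 3 interferon-stimulated genes lower adjusted over the list alone.

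With lactate present the calls of Egln3 and Ankrd37 held in all 23 alternatives. Fitting only the 2 groups compared ended the others, at edgeR BH-adjusted p of 0.067 for Pdk1, 0.262 for Ak4, Pfkfb3, Slc2a1 and Cx3cr1, 0.284 for Slc16a3, 0.385 for Vegfa, 0.412 for Ldha, 0.612 for Ctsk and 0.722 for Lgals9, each the highest over its alternatives except for Cx3cr1. Leaving out normoxia-lactate 1 ended the calls of Pdk1 (0.0531), Pfkfb3 (0.073), Ak4 (0.106), Slc2a1 (0.106), Slc16a3 (0.108), Vegfa (0.131), Lgals9 (0.131), Ldha (0.311), Cx3cr1 (0.362) and Ctsk (0.362). Leaving out normoxia-lactate 2 ended those of Ak4 (0.056), Vegfa (0.0613), Ldha (0.0834), Cx3cr1 (0.0987), Lgals9 (0.228) and Ctsk (0.259), and leaving out normoxia-lactate 3 those of Ak4 (0.0789), Slc2a1 (0.087), Slc16a3 (0.087), Vegfa (0.125), Ctsk (0.125), Lgals9 (0.184), Ldha (0.239) and Cx3cr1 (0.277). Ldha was also at 0.081, 0.0735 and 0.0663 without hypoxia-NaCl 1, 2 and 3, at 0.0746 without normoxia-NaCl 2, and at 0.0791 with the library number as a block. Cx3cr1 was at 0.0815 and 0.085 without hypoxia-NaCl 1 and 2, 0.0676 and 0.0746 without normoxia-NaCl 1 and 2, 0.0741 without hypoxia-lactate 1, 0.0505 with RLE size factors and 0.0667 with the block. Ctsk was at 0.105, 0.087 and 0.0876 without hypoxia-NaCl 1, 2 and 3, 0.0805, 0.0763 and 0.0666 without normoxia-NaCl 1, 2 and 3, 0.059 without hypoxia-lactate 1 and 0.0587 with RLE size factors. Lgals9 was at 0.105, 0.0941 and 0.0876 without hypoxia-NaCl 1, 2 and 3, 0.0676, 0.0746 and 0.0734 without normoxia-NaCl 1, 2 and 3, 0.0908 without hypoxia-lactate 1, 0.0711 with upper-quartile factors and 0.0782 by limma-voom.

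With lactate in normoxia 7 gene lists passed camera's test with the preset correlation. With an estimated correlation none of them did unless the library number was a block too. No single gene passed edgeR's test. All 30 cell cycle genes were lower with lactate, by a median of -0.70 (camera adjusted p = 5.63e-19; adjusted p = 0.403 with an estimated correlation, and 0.0161 with the library number as a block too). Same-numbered libraries correlated at 0.025 to 0.239 in this comparison, so that block rests on a pairing that missed the limit of 0.1. The proliferation marker Mki67 was at 142 ± 20.8 CPM with lactate against 230 ± 62.2 CPM without it (SD, n = 3 each; log2 change -0.70 ± 0.25), and Top2a, a topoisomerase of dividing cells, at 68.5 ± 13.3 against 122.6 ± 43.1 CPM. Both were chosen after their values were seen. The median stayed between -0.88 and -0.40 with each library left out in turn, the latter without normoxia-NaCl 2. Of the 30 genes 7 were lower at an unadjusted p under 0.05, and 0 passed by edgeR over all genes or adjusted over the list alone, by DESeq2 or by limma-voom. Without hypoxia-lactate 3, 13 of the 30 were lower by edgeR adjusted over the list alone, and 0 over all genes.

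Nuclear-encoded oxidative phosphorylation (29 of 31 genes negative, median -0.28, camera adjusted p = 7.67e-07; adjusted p = 0.403 with an estimated correlation), the lysosome list (20 of 24, -0.23, 0.000394; adjusted p = 0.406 with an estimated correlation) and macrophage identity (14 of 19, -0.29, 0.00129; adjusted p = 0.403 with an estimated correlation) were lower. Without normoxia-NaCl 1 these 3 lists had medians of -0.06, -0.03 and -0.14 and camera adjusted p of 0.213, 0.419 and 0.137. The oxidative phosphorylation median was -0.43 and -0.45 without normoxia-NaCl 2 and 3, and the lysosome median -0.34 without normoxia-NaCl 2. Interferon-stimulated genes were lower (median -0.22, camera adjusted p = 0.0041; adjusted p = 0.403 with an estimated correlation), at 0.345 without normoxia-NaCl 2 and with a median of -0.37 without normoxia-NaCl 3. Alternative activation (16 genes, -0.24, camera adjusted p = 0.0311; adjusted p = 0.403 with an estimated correlation) had 1 gene lower adjusted over the list alone. It was at 0.0727, 0.0746, 0.16 and 0.382 without hypoxia-lactate 3, normoxia-NaCl 1, normoxia-NaCl 2 and normoxia-lactate 3, with medians of -0.18, -0.10, -0.13 and -0.10, and its median was -0.40 without normoxia-lactate 2. ATF4 response genes (22 genes, -0.25, camera adjusted p = 0.046; adjusted p = 0.739 with an estimated correlation) were at 0.0727, 0.213, 0.16, 0.0871 and 0.571 without hypoxia-lactate 3, normoxia-NaCl 1 and 2, and normoxia-lactate 1 and 3. The median was -0.13 without normoxia-lactate 3 and -0.44 without normoxia-lactate 2. Without hypoxia-lactate 3, 5 macrophage identity genes were lower and 1 higher, 2 alternative activation genes lower and 1 interferon-stimulated gene lower, all adjusted over the list alone. Mitochondrially encoded genes were higher without both outlying libraries (median 0.52, camera adjusted p = 4.06e-15, against 0.852; adjusted p = 0.795 with an estimated correlation). Glycolysis (median -0.003, camera adjusted p = 0.852) and other HIF targets (0.12, 0.351) did not pass.

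Of single genes edgeR called 0 higher and 0 lower with lactate in normoxia, 227 had an unadjusted p under 0.05, limma-voom called 0, and DESeq2 called 6 higher and 4 lower. Without hypoxia-lactate 3 edgeR called 4 higher and 1 lower, and without both outlying libraries 2 and 1. With all libraries a 4-fold change of simulated, well-counted genes was recovered in 70% of cases and a 2-fold change in 6% (14409 simulated genes tested). A 2-fold change was thus mostly not detectable in that fit. Without hypoxia-lactate 3 the recovery was 97% and 65% (14820 tested).

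Lactate in hypoxia was tested between hypoxia-lactate and hypoxia-NaCl. Lists again passed camera's test with the preset correlation alone, without single-gene calls. ATF4 amino acid response genes were higher, 20 of 22 of them positive with a median of 0.34 (camera adjusted p = 0.00584; adjusted p = 0.716 with an estimated correlation). They were at 0.116 without hypoxia-NaCl 3 and 0.446 without hypoxia-lactate 2, with medians of 0.18 and 0.09, and the median was 0.65 without hypoxia-NaCl 2. NRF2 antioxidant genes were higher (11 of 14, 0.35, camera adjusted p = 0.0254; adjusted p = 0.716 with an estimated correlation), at 0.08 and 0.446 without hypoxia-lactate 1 and 2, with a median of 0.10 without the latter. Interferon-stimulated genes were lower (19 of 26, -0.43, camera adjusted p = 0.00583; adjusted p = 0.716 with an estimated correlation), at 0.182 without hypoxia-lactate 2, with medians of -0.80 without hypoxia-lactate 1 and -0.28 without hypoxia-lactate 3.

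Glycolysis (19 of 23 positive, median 0.36, camera adjusted p = 0.000603), other HIF targets (19 of 24, 0.43, 0.00306) and endoplasmic reticulum chaperones (14 of 17, 0.26, 0.0029) were higher with lactate in hypoxia, each with adjusted p = 0.716 with an estimated correlation. Without hypoxia-lactate 3 their medians were 0.06, 0.00 and 0.14 and their camera adjusted p 0.261, 0.341 and 0.0668. The HIF list was at 0.0862 without hypoxia-NaCl 2, with a median of 0.70 without hypoxia-NaCl 3, and the chaperone median was 0.40 without hypoxia-lactate 1. Cell cycle genes, with a median of -0.37 (camera adjusted p = 0.0662), passed with the library number as a block (0.00166; adjusted p = 0.42 with an estimated correlation) and without hypoxia-lactate 3 (median -0.30, camera adjusted p = 0.00893; adjusted p = 0.854 with an estimated correlation). Without that library macrophage identity was lower too (median -0.37, 8 lower adjusted over the list alone, camera adjusted p = 0.000358, against 0.494) and the pro-inflammatory list higher (0.33, 2 higher adjusted over the list alone, 0.00686, against 0.125), each with adjusted p = 0.681 with an estimated correlation. With both outlying libraries left out mitochondrially encoded genes were higher (median 0.26, camera adjusted p = 0.000142) and the lysosome list lower (-0.08, 0.0479), each with adjusted p = 0.733 with an estimated correlation. The chaperones then passed (0.13, 0.0486; adjusted p = 0.803 with an estimated correlation). For single genes edgeR called 0 higher and 0 lower, with 1664 at an unadjusted p under 0.05, limma-voom 0, and DESeq2 51 higher and 61 lower. Without hypoxia-lactate 3 edgeR called 3 and 3, without both outlying libraries 5 and 6.

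Hypoxia and lactate together, hypoxia-lactate against normoxia-NaCl, gave the most calls of the 6 comparisons, except when only the 2 groups compared were fitted (6 genes, against 59 for hypoxia without lactate). Egln3 rose by 5.14 ± 0.26 and Ankrd37 by 5.11 ± 0.31, and Hspa1a (ENSMUSG00000091971) and Hspa1b (ENSMUSG00000090877) by 3.64 ± 0.37 and 3.64 ± 0.34. Hspa1a went from 20.4 ± 1.94 to 255 ± 122 CPM (SD, n = 3 each). Vegfa rose by 3.02 ± 0.38, Slc16a3 by 3.16 ± 0.39, Ak4 by 4.21 ± 0.53, the collagenase Mmp13 by 3.46 ± 0.66 and the cytokine Il1b by 2.88 ± 0.46. The rise of Mmp13 was 2.21 to 3.77 over its alternatives. Mrc1 (ENSMUSG00000026712), the mannose receptor and a marker of alternative activation, fell from 23.4 ± 2.68 to 3.41 ± 2.34 CPM (SD, n = 3 each), a log2 change of -2.76 ± 0.46. Cd33 (ENSMUSG00000004609), a sialic acid-binding receptor, fell too (-2.47 ± 0.29), as did Lgals9 (-2.24 ± 0.27), the urokinase gene Plau (-4.28 ± 0.84), the interleukin 12 receptor subunit Il12rb2 (-2.65 ± 0.50) and Wfdc17 (-2.43 ± 0.43). In all 171 genes were higher and 64 lower, 201 of these 235 by at least 2-fold, with edgeR BH-adjusted p from 8.34e-07 for Egln3 to 0.0256 for Plau among these.

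By list, 12 of 24 other HIF targets rose (18 higher and 1 lower adjusted over the list alone; median 2.07, camera adjusted p = 2.65e-21; adjusted p = 0.0708 with an estimated correlation) and 12 of 23 glycolysis genes (16 adjusted over the list alone; 1.34, camera adjusted p = 5.01e-19; adjusted p = 0.126 with an estimated correlation). Among the latter were Pdk1 (2.29 ± 0.24) and Slc2a1 (2.28 ± 0.26). The medians were 1.655 for other HIF targets and 1.085 for glycolysis without hypoxia-lactate 3. Of 8 lactate transport and interconversion genes Slc16a3 and Ldha (1.77 ± 0.30) rose and Ldhb, the dehydrogenase subunit B, fell (-1.96 ± 0.38); the list, with 3 higher and 1 lower adjusted over the list alone, did not pass (camera adjusted p = 0.343). The pro-inflammatory list was higher, 3 of 21 risen (6 higher and 3 lower adjusted over the list alone; median 0.75, camera adjusted p = 0.00308; adjusted p = 0.516 with an estimated correlation), led by Il1b (edgeR BH-adjusted p = 0.00887). Interferon-stimulated genes were lower, with Zbp1, a sensor of Z-form nucleic acid, the 1 of 26 that fell (4 adjusted over the list alone; median -0.69, camera adjusted p = 1.74e-05; adjusted p = 0.156 with an estimated correlation; median -1.04 without hypoxia-lactate 1). Cell cycle genes were lower, with the mitotic kinase Cdk1 the 1 of 30 that fell (3 adjusted over the list alone; median -0.88, camera adjusted p = 5.23e-06; adjusted p = 0.516 with an estimated correlation; median -0.55 without normoxia-NaCl 2). The calls of Zbp1 (edgeR BH-adjusted p = 0.0488) and Cdk1 (0.0401) were lost without any 1 of the hypoxia-NaCl, normoxia-NaCl and normoxia-lactate libraries, at 0.0719 to 0.148 and 0.0535 to 0.133, and that of Zbp1 also without hypoxia-lactate 2 (0.0596). Both were also lost with upper-quartile factors (0.0554 and 0.0567), by limma-voom (0.0563 and 0.0666) and when the 2 groups alone were fitted (0.501 and 0.446), and Zbp1 with RLE size factors (0.0507) and no filter (0.0626). Over all alternatives the ranges were 0.000102 to 0.501 and 0.000461 to 0.446. Without hypoxia-lactate 3, 7 pro-inflammatory genes rose and Marco, a scavenger receptor, fell (10 higher and 3 lower adjusted over the list alone). The interferon-stimulated genes that fell were then Bst2, Irf7, Oas3, Oasl2 and Zbp1 (12 lower adjusted over the list alone), and the cell cycle genes Cdc20, Cdk1, Mcm4, Mcm5 and Nusap1 (16 lower and 1 higher adjusted over the list alone). In the alternative activation list Mrc1 and the transglutaminase Tgm2 (-1.51 ± 0.19) fell, 2 of 16 (1 higher and 2 lower adjusted over the list alone, 3 and 2 of 17 without hypoxia-lactate 3), and the list did not pass (median -0.28, camera adjusted p = 0.343). Without hypoxia-lactate 3 the median of that list was -0.17 (camera adjusted p = 0.534).

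Of 19 macrophage identity genes Cx3cr1 (2.02 ± 0.28) and the lipopolysaccharide co-receptor Cd14 (1.27 ± 0.24) rose and the signalling adaptor Tyrobp (-1.15 ± 0.19) fell, with 3 higher and 5 lower adjusted over the list alone (median -0.31, camera adjusted p = 0.343). Without hypoxia-lactate 3 the list was lower (median -0.56, camera adjusted p = 0.00165; adjusted p = 0.575 with an estimated correlation), with 2 higher and 6 lower, 3 and 11 adjusted over the list alone. Nuclear-encoded oxidative phosphorylation was lower (median -0.55, camera adjusted p = 0.000148; adjusted p = 0.516 with an estimated correlation; -0.26 without normoxia-NaCl 1). Cholesterol synthesis (median -0.57, camera adjusted p = 0.00308) and the lysosome (-0.34, 0.00308) were lower, each with adjusted p = 0.516 with an estimated correlation. The first was at 0.0555 without hypoxia-lactate 1, and the second at 0.0891 and 0.132 without hypoxia-lactate 2 and normoxia-NaCl 1, with medians of -0.20 and -0.14. Endoplasmic reticulum chaperones were higher (0.18, camera adjusted p = 0.0164; adjusted p = 0.516 with an estimated correlation), at 0.0527, 0.333 and 0.15 without hypoxia-lactate 2 and 3 and normoxia-NaCl 3, with a median of 0.29 without normoxia-NaCl 1. Mitochondrially encoded genes were lower (-0.75, camera adjusted p = 0.0164; adjusted p = 0.6 with an estimated correlation), with medians of -0.28 (0.691) without hypoxia-lactate 3 and -0.05 (0.475) without normoxia-NaCl 1, the libraries with the lowest and highest mitochondrial shares. Without both, the direction turned and the list was higher (median 0.36, camera adjusted p = 8.84e-05; adjusted p = 0.459 with an estimated correlation). In the tricarboxylic acid cycle list Idh2, the mitochondrial isocitrate dehydrogenase, fell (-1.11 ± 0.20), and the list did not pass (1 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.343). Without hypoxia-lactate 3, Fh1, Mpc1 and Suclg2 fell there too and Idh1 rose (2 higher and 5 lower adjusted over the list alone). Sdhc of oxidative phosphorylation and Mvk of cholesterol synthesis then fell, with 8 and 4 genes of these lists lower adjusted over the list alone.

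For hypoxia and lactate together, 543 genes were higher and 492 lower without hypoxia-lactate 3, all 235 calls among them, and 481 and 431 without both outlying libraries. With the library number as a block 222 were higher and 113 lower, 216 of them shared with the 235. With upper-quartile factors the split was 118 higher and 79 lower, 59.9% higher against 72.8%, and the median of all genes was -0.13 with that scaling. The total also moved by more than 1.5-fold without hypoxia-NaCl 1 or 2 (128, 130), hypoxia-lactate 2 (690), normoxia-NaCl 1, 2 or 3 (78, 90, 67) or normoxia-lactate 1, 2 or 3 (125, 142, 144). The calls of Egln3, Ankrd37, Hspa1a and Hspa1b held in all 23 alternatives, and fitting only the 2 groups compared was the only 1 to end those of Ak4 (edgeR BH-adjusted p = 0.0523), Pdk1 (0.0523), Slc2a1 (0.0583), Slc16a3 (0.0794), Vegfa, Cd33, Lgals9, Tgm2 and Cx3cr1 (0.126 each), Mrc1 (0.253) and Tyrobp (0.295), each the highest value over its alternatives. That fit also ended Mmp13 (0.199), Il1b (0.252), Ldha (0.271), Plau (0.293), Wfdc17 (0.295), Il12rb2 (0.321), Cd14 (0.34), Idh2 (0.38) and Ldhb (0.437), again the highest values. Leaving out normoxia-NaCl 1, 2 and 3 gave 0.122, 0.0791 and 0.0847 for Mmp13, 0.0739, 0.0642 and 0.0576 for Idh2, and 0.064, 0.0805 and 0.0868 for Ldhb. Normoxia-NaCl 2 and 3 gave 0.0885 and 0.0677 for Plau, 0.0642 and 0.0651 for Ldha, and 0.101 and 0.0964 for Cd14. Normoxia-NaCl 1 and 3 gave 0.0919 and 0.0583 for Il12rb2, normoxia-NaCl 1 and 2 gave 0.0552 and 0.0642 for Wfdc17. Normoxia-NaCl 3 gave 0.0583 for Il1b. Without hypoxia-lactate 1 Plau was at 0.0552, Cd14 at 0.0533 and Ldhb at 0.0554. Ldhb was also at 0.0511 and 0.0524 without hypoxia-NaCl 1 and 2 and at 0.0547 and 0.0511 without normoxia-lactate 1 and 2.

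**Figure D2:**
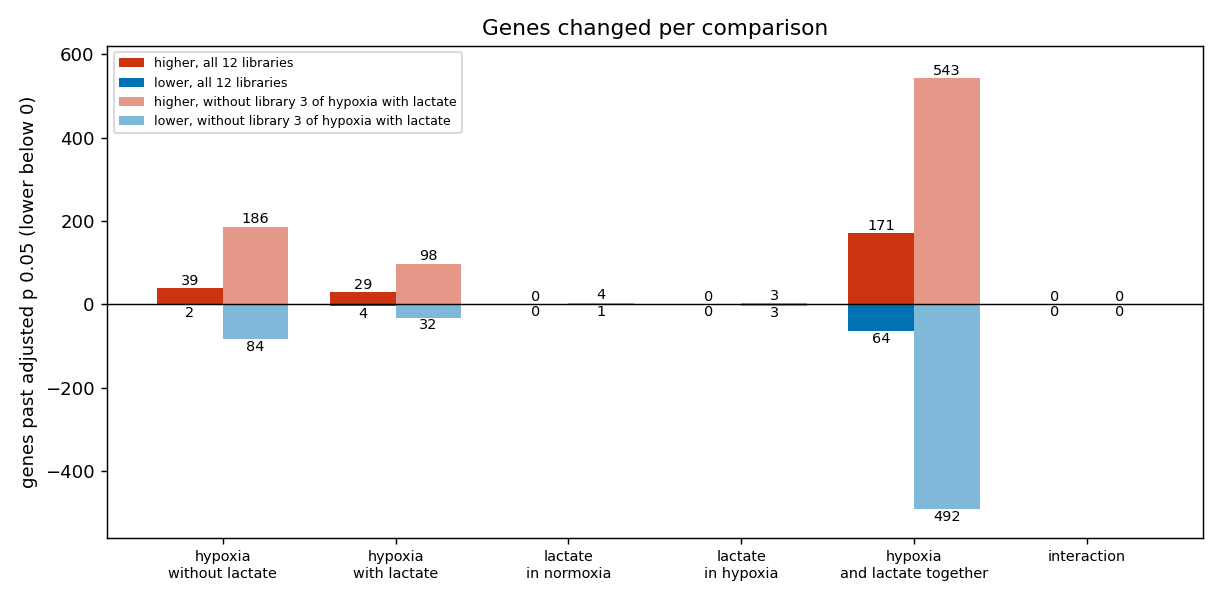
Genes past an adjusted p of 0.05 (edgeR) in each of the 6 comparisons, higher above 0 and lower below 0, with all 12 libraries and with hypoxia-lactate 3 left out. Hypoxia and lactate together had 171 higher and 64 lower genes with all libraries and 543 and 492 without that library.

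The interaction asks whether the effect of low oxygen differed with lactate, as a departure from the product of the 2 folds. ATF4 amino acid response genes had 21 of 22 members positive and a median of 0.55 (camera adjusted p = 0.000317; adjusted p = 0.807 with an estimated correlation), with a median of -0.45 for low oxygen without lactate and 0.19 with it. Endoplasmic reticulum chaperones had a median of 0.41 (14 of 17 positive, camera adjusted p = 0.000317), glycolysis 0.36 (19 of 23, 0.00214), nuclear-encoded oxidative phosphorylation 0.19 (21 of 31, 0.0313) and cell cycle 0.28 (22 of 30, 0.0366), each with adjusted p = 0.807 with an estimated correlation. ATF4 genes were at 0.111 without hypoxia-lactate 2 (median 0.13), with medians of 0.32 and 0.35 without hypoxia-NaCl 3 and normoxia-lactate 3. Chaperones had a median of 0.19 and glycolysis of 0.12 (0.364) without hypoxia-lactate 3, and glycolysis of 0.21 and 0.55 without normoxia-NaCl 1 and hypoxia-lactate 2. Oxidative phosphorylation was at 0.077, 0.167, 0.111, 0.832 and 0.101 without hypoxia-NaCl 1, hypoxia-lactate 1 and 2, normoxia-NaCl 1 (median 0.06) and normoxia-lactate 1 (0.12). Cell cycle was at 0.402, 0.202, 0.159, 0.694 and 0.325 without hypoxia-NaCl 3, hypoxia-lactate 1 and 2, normoxia-NaCl 2 and normoxia-lactate 3, with medians of 0.07, 0.10, 0.16, -0.03 and 0.13, and its median was 0.44 and 0.48 without hypoxia-NaCl 2 and normoxia-NaCl 3 and 0.17 with the library number as a block. Without hypoxia-lactate 3 the tricarboxylic acid cycle (median 0.18, camera adjusted p = 0.0035, against 0.0968), cholesterol synthesis (0.13, 0.0284, against 0.171) and NRF2 lists (0.32, 0.00106, against 0.0968) passed, with adjusted p = 0.914, 0.914 and 0.756 with an estimated correlation. Without both outlying libraries only the NRF2 list of these 3 passed (0.00305), and MHC class II (-0.62, 0.0325) and macrophage identity (-0.15, 0.034) were lower, each with adjusted p = 0.919 with an estimated correlation. No single gene passed. EdgeR called 0 higher and 0 lower, with all libraries and with any 1 left out, while 497 had an unadjusted p under 0.05. Limma-voom called 0, and DESeq2 called 1, the predicted gene Gm14111 (log2 3.45 ± 0.64, adjusted p = 0.00087), chosen after its value was seen. Of simulated 4-fold interactions 40% were recovered, and 2% of 2-fold (14435 simulated genes tested), against 82% and 24% without hypoxia-lactate 3 (14824 tested).

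**Figure D3:**
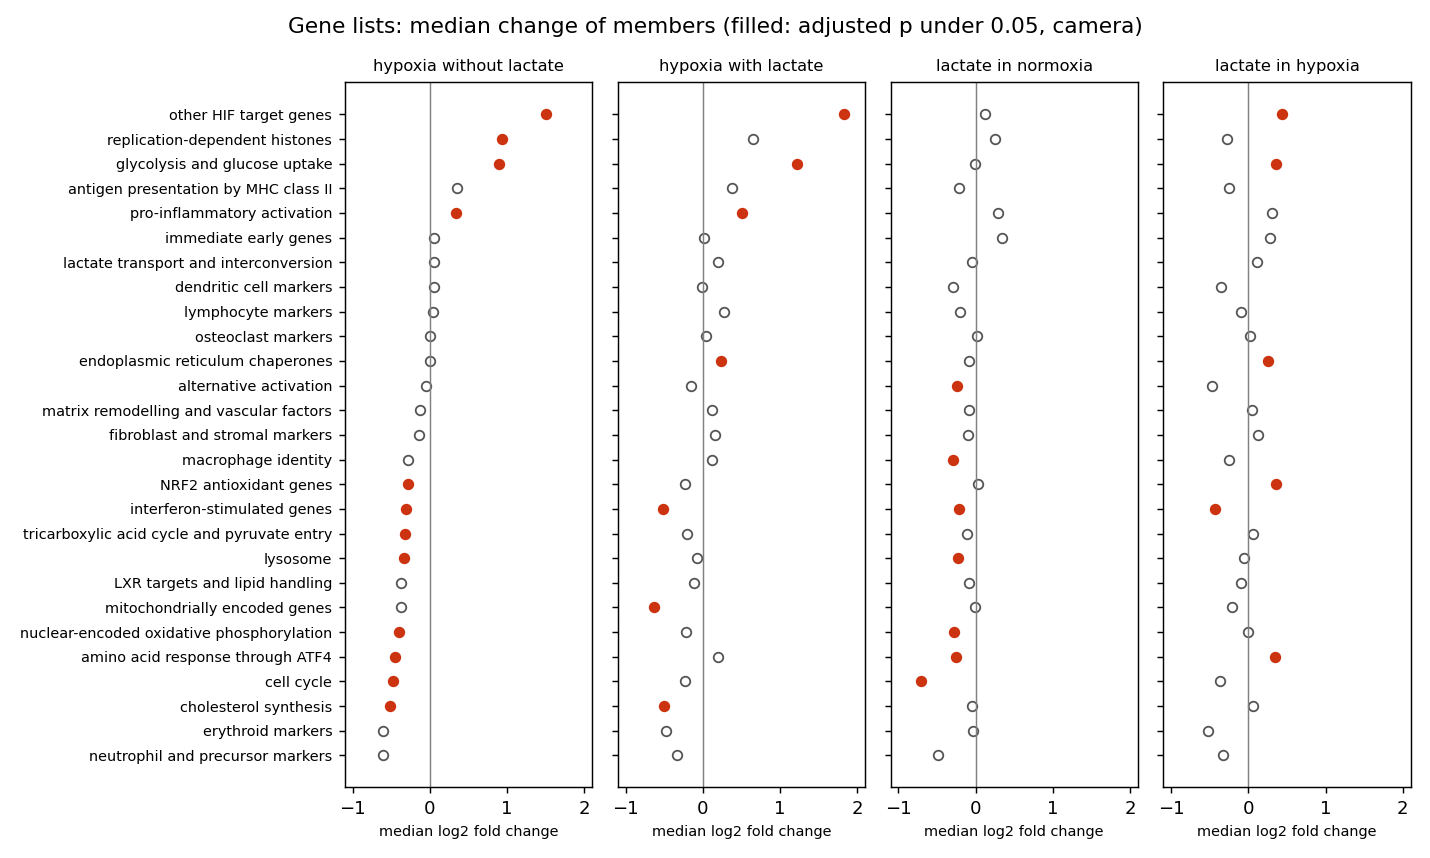
Median log2 fold change of the members of each gene list, 1 point per list, filled where camera gave an adjusted p under 0.05. The comparisons shown are hypoxia without lactate, hypoxia with lactate, lactate in normoxia and lactate in hypoxia. With low oxygen without lactate other HIF targets lie at 1.5 and glycolysis at 0.89, and the cell cycle list lies at -0.70 with lactate in normoxia.

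Of the genes fixed as markers, Mrc1 had its highest level in normoxia-NaCl, 23.4 ± 2.68 CPM, and was at 11.9 ± 1.60 in normoxia-lactate, 9.81 ± 3.17 in hypoxia-NaCl and 3.41 ± 2.34 in hypoxia-lactate (SD, n = 3 each). With all libraries its change passed edgeR's test for both conditions together alone (BH-adjusted p = 0.012). It was -1.25 ± 0.44 for low oxygen without lactate (0.559), -0.98 ± 0.43 for lactate in normoxia (1; 0.0332 to 1 over its alternatives, the lowest, and only call, with library quality weights in limma-voom), -1.51 ± 0.45 for lactate in hypoxia (0.432) and -1.79 ± 0.45 for low oxygen with lactate (0.171). The first passed without hypoxia-lactate 3 (0.0304; 0.000376 to 1 over its alternatives) and the last without hypoxia-lactate 2 (0.0431; 0.00321 to 0.741). Vegfa was at 49.5 ± 10.1, 72.7 ± 20.4, 201 ± 19.8 and 402 ± 248 CPM and Slc2a1 at 78.7 ± 1.12, 101 ± 21.4, 294 ± 68.3 and 382 ± 128 CPM in normoxia-NaCl, normoxia-lactate, hypoxia-NaCl and hypoxia-lactate (SD, n = 3 each). Their lactate effects did not pass. Vegfa was at 0.55 ± 0.35 in normoxia and 1.00 ± 0.36 in hypoxia, Slc2a1 at 0.36 ± 0.25 and 0.38 ± 0.25. The values in hypoxia ranged from 0.363 to 1.257 for Vegfa and from 0.067 to 0.561 for Slc2a1 over the alternatives. Hypoxia-lactate 1, 2 and 3 held 252, 265 and 687 CPM of Vegfa and 304, 313 and 529 CPM of Slc2a1. Nos2 (ENSMUSG00000020826), inducible nitric oxide synthase, stayed below 10 CPM, at 0.0702 ± 0.122, 0.152 ± 0.05, 1.03 ± 0.548 and 2.85 ± 2.93 CPM in the same order, and its change of 5.23 ± 1.23 for both conditions missed the threshold (edgeR BH-adjusted p = 0.0566). That change was 3.99 to 9.71 over its alternatives, and normoxia-NaCl held 8 counts of Nos2, all in normoxia-NaCl 2. Nos2 passed there without hypoxia-lactate 2 (0.0414), hypoxia-lactate 3 (0.00665) or normoxia-NaCl 2 (0.0411), over a range of 0.000102 to 0.505, and for low oxygen with lactate without hypoxia-lactate 3 (0.0337 against 0.205; 0.00282 to 0.741). Hif1a (ENSMUSG00000021109), the oxygen-regulated HIF subunit, was at 38.2 ± 3.96, 45.7 ± 5.21, 39.3 ± 3.93 and 51.8 ± 14.2 CPM, and for both conditions its change was 0.44 ± 0.22 (edgeR BH-adjusted p = 0.285, and 0.0252 without hypoxia-lactate 3; 0.0154 to 0.665 over its alternatives).

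Arg1 (ENSMUSG00000019987), arginase 1, a marker of tumour-associated macrophages, was too low to be tested. Over the 3 libraries of each group it had 0 counts in normoxia-NaCl, where 3 counts would be 0.0275 CPM, 2 in normoxia-lactate (0.0144 CPM pooled), 28 in hypoxia-NaCl (0.258) and 33 in hypoxia-lactate (0.434), each over the summed library totals without TMM factors. In hypoxia-NaCl libraries 1 to 3 held 8, 1 and 19 of these counts, and in hypoxia-lactate 0, 31 and 2. Such floors cover counting error only.

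**Figure D4:**
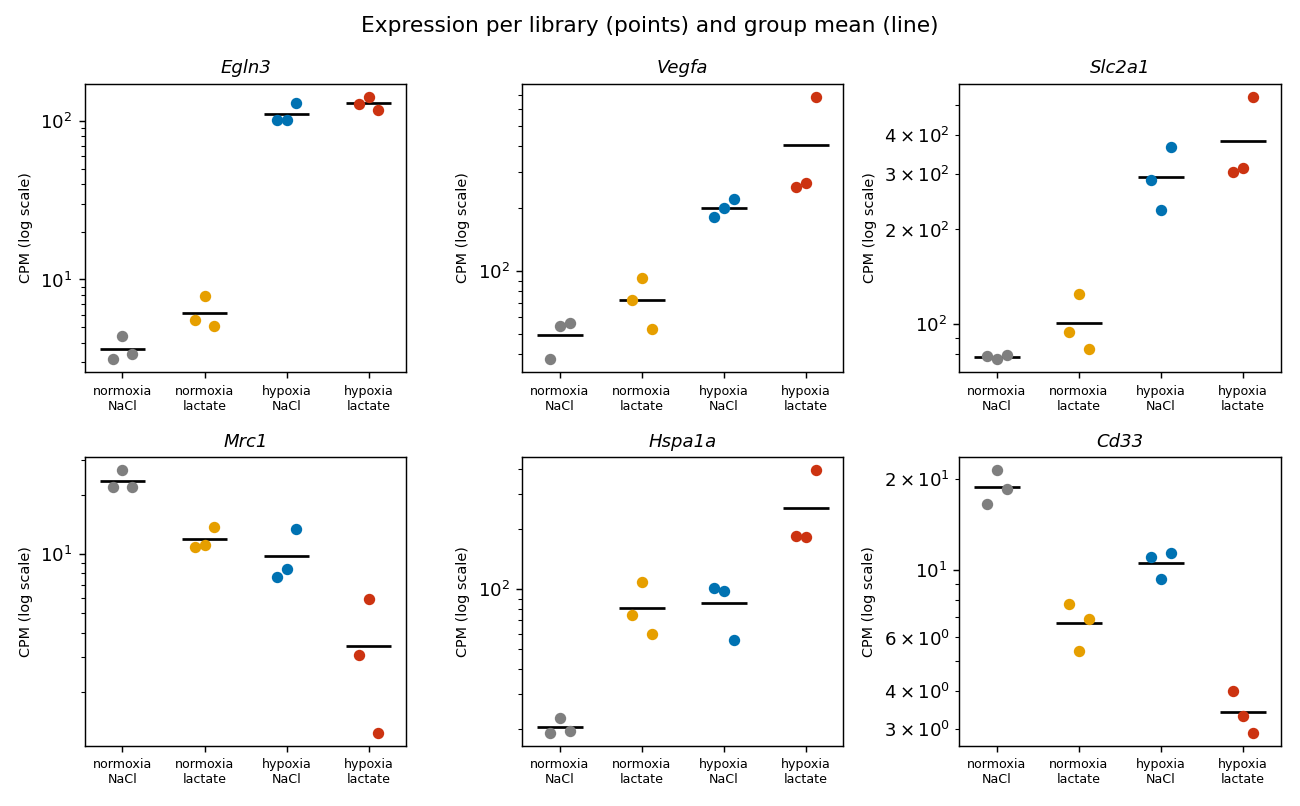
Expression in CPM on a log scale of Egln3, Vegfa, Slc2a1, Mrc1, Hspa1a and Cd33 in the 4 groups, 1 point per library with a line at the group mean. Egln3 is at 3.66 CPM on average in normoxia-NaCl and 110 in hypoxia-NaCl, and Mrc1 at 23.4 CPM in normoxia-NaCl and 3.41 in hypoxia-lactate.

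Across 14616 genes, which are not independent replicates, the log2 changes under low oxygen with and without lactate had a Pearson r of 0.226 (0.388 without hypoxia-lactate 3; covariance 0.0953), with no library in common. Those of lactate in normoxia and in hypoxia had an r of 0.03 (0.206 without hypoxia-lactate 3). All 39 higher and 2 lower genes of low oxygen without lactate were also called in the same direction for both conditions together, which share the normoxia-NaCl libraries. Independent lists would share 0.456 and 0.00876, and 10 simulations of unchanged groups against the same controls shared 0 and 0, neither of which allows for effects and shared controls at once. The log2 changes of these comparisons had an r of 0.494 and a covariance of 0.226, against simulated means of 0.49 and 0.139, and part of the overlap may come from the shared controls. Low oxygen and lactate, each against normoxia-NaCl, had an r of 0.612 and a covariance of 0.131, where unchanged groups simulated against the same 3 controls gave 0.502 and 0.14.

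No tested list of markers of other cell types passed camera's test for both conditions together with all libraries, which does not show that their levels stayed the same. For both conditions together camera adjusted p was 0.401 for neutrophil and precursor markers (12 genes tested, median -1.14), 0.962 for fibroblast and stromal markers (10), 0.401 for lymphocyte markers (6), 0.455 for dendritic cell markers (7), 0.368 for erythroid markers (3) and 0.506 for osteoclast markers (8). Of mast cell and basophil markers only 1 gene was expressed enough to test. Neutrophil markers passed for lactate in normoxia with the library number as a block alone (median -0.48, camera adjusted p = 0.0224, against 0.324; adjusted p = 0.342 with an estimated correlation). All 12 were lower there with all libraries. With both outlying libraries left out their median was -1.078 for lactate in normoxia and -0.9 for hypoxia without lactate. It was 0.217 for lactate in hypoxia and 0.051 for hypoxia with lactate, and none of these passed (camera adjusted p of 0.35 to 0.924). Among osteoclast markers Ctsk rose (2.33 ± 0.32, edgeR BH-adjusted p = 0.00379, lost only when the 2 groups alone were fitted, 0.129), and among lymphocyte markers Klrb1c, a natural killer cell receptor, rose from 0.718 ± 0.263 to 4.46 ± 2.39 CPM (SD, n = 3 each). The Klrb1c call (edgeR BH-adjusted p = 0.0315) was lost without hypoxia-NaCl 1, 2 or 3 (0.0656, 0.0629, 0.0545), normoxia-NaCl 1, 2 or 3 (0.0739, 0.119, 0.125) or normoxia-lactate 1 or 2 (0.0654, 0.0551), or when the 2 groups alone were fitted (0.411), over a range of 7.28e-06 to 0.411. The lists of LXR targets and lipid handling (18 genes, camera adjusted p = 0.527), matrix remodelling and vascular factors (27, 0.368), immediate early genes (11, 0.114), NRF2 antioxidant genes (14, 0.904), ATF4 response genes (22, 0.904), MHC class II (12, 0.774) and histones (3, 0.343) did not pass for both conditions together.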

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

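The tests of a normoxic library under a wrong label, of shared Hspa1a and Hspa1b reads, of low Hspa1 levels in the controls alone, of heat shock factor targets under each treatment by itself or without hypoxia-lactate 3, and of normoxia-NaCl 1 as the source of the cell cycle change were chosen only after the result was seen. Groups of 3 libraries were each too small by themselves to test for a single sample far from the others. Over all libraries the limma-voom quality weight was lowest for hypoxia-lactate 3 (0.0482) and next lowest for normoxia-NaCl 1 (0.299). Under this heading ± is the SD over resampled genes, which holds no spread between libraries, except where another is named.

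For 5 gene lists the effect of low oxygen differed with lactate by camera's test of the interaction. The median log2 difference was 0.55 for ATF4 amino acid response genes, 0.411 for endoplasmic reticulum chaperones, 0.364 for glycolysis, 0.185 for nuclear-encoded oxidative phosphorylation and 0.282 for cell cycle genes, each with an adjusted p = 0.807 with an estimated correlation. Leaving out hypoxia-lactate 2 gave 0.13 for the ATF4 genes (camera adjusted p = 0.111), and leaving out hypoxia-lactate 3 gave 0.19 for chaperones and 0.12 for glycolysis (0.364). For oxidative phosphorylation the median was 0.06 (0.832) without normoxia-NaCl 1, and for cell cycle -0.03 (0.694) without normoxia-NaCl 2.

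Hypoxia-lactate 3 stood apart from the other libraries. A normoxic library under this label was excluded: over HIF targets it lay at a median fraction of 1.15 ± 0.127 of the shift from normoxia-lactate to the other hypoxia-lactate libraries, where a normoxic library would lie near 0. Few distinct molecules in the library may explain part of its spread. Its excess squared log2 deviation was 8.52 ± 1.58 times as large for genes of 10 to 30 CPM as for the most abundant ones. Those most abundant genes still had a log2 spread of 0.632, against at most 0.503 in the libraries it was compared with. Its mitochondrial share was 0.486%, against 3.098% and 2.922% in hypoxia-lactate 1 and 2. The ratio does not account for these 2 differences, so part of this library's spread stays open. GC content and transcript length explained 9.45% ± 0.565 of the variance of its deviations, too near the 10% set as the bound to exclude a part. No biological explanation was tested, since the labels give this library no treatment of its own.

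Hspa1a, Hspa1b and Hspa1l, inducible or testis-type HSP70 genes, were higher under both treatments. Reads moving between Hspa1a and Hspa1b were excluded as the whole cause, since the sum of both rose by a log2 of 3.59 ± 0.282 (SE over libraries). For low levels in normoxia-NaCl alone, the 2 comparisons without those libraries gave a median of 1.37 over the 3 genes. Its ± of 0.0694 takes related values as independent and holds no spread between libraries. Singly the values were 1.25 to 1.65, with SE of 0.256 to 0.338, and none passed (edgeR BH-adjusted p of 0.0975 to 0.432). With hypoxia-lactate 3 left out, Hspa1l passed for hypoxia with lactate (1.265, SE 0.208, edgeR BH-adjusted p = 0.0134). The others did not pass (edgeR BH-adjusted p of 0.0522 to 0.271). For each of the 3 genes every hypoxia-lactate library lay above every normoxia-lactate and hypoxia-NaCl library. All values were positive, which goes against that cause but does not exclude it. For a general heat shock response the test with all libraries and both treatments could not decide. The 11 other heat shock factor targets had a median of 0.133 ± 0.268, with 6 positive and 1 called. The bound was at least 0.5 for such a response and under 0.2 against it. Their median was -0.03 ± 0.221 without hypoxia-lactate 3 (4 positive, 1 called). It was -0.21 ± 0.157 for hypoxia without lactate (3 positive, 0 called) and -0.14 ± 0.138 for lactate in normoxia (4 positive, 0 called). Each lies under the 0.2 bound beyond its spread, which argues against a general response of these targets there. That spread holds none between libraries, and members went both ways in each. A response of the HSP70 genes to each treatment is a hypothesis, found and tested on the same libraries.

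Cell cycle genes were lower with lactate in normoxia. The outlying library normoxia-NaCl 1 was excluded as the source, since the median was -0.772 ± 0.0863 without it, a spread over genes and not libraries. Per library the median deviation of the list was 0.34, 1.076 and 0.13 in normoxia-NaCl 1, 2 and 3. In normoxia-lactate 1, 2 and 3 it was -0.154, 0.193 and -0.398, so the groups overlapped. Normoxia-NaCl 2 carried part of the difference, with a median of -0.40 without it. A lower share of dividing cells with lactate may explain the rest of the change and was not tested further.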

How the results depend on the processing

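Leaving out both outlying libraries, quality weights and the block without hypoxia-lactate 3 were chosen after seeing the data. The cause was not tested for any change given here. Of the named genes, 1759 values kept their direction and side of the threshold, 84 came to pass it, 258 no longer passed and 21 changed sign; of list results 550 kept both and 108 no longer passed, 45 of them with an estimated correlation. Averaged over the other groups, deviations of 12 of 12 libraries correlated best with their own number, a hint from the data and not the design (same-number correlations -0.069 to 0.404, 12 of 18 over 0.1). Singly, hypoxia-lactate 3 and normoxia-NaCl 1 correlated best with each other (0.142). With that number as a block the counts were 39 and 2 higher and lower for hypoxia without lactate, 32 and 2 for hypoxia with lactate, 222 and 113 for both together and 0 for the others. They shared 31 of 41, 25 of 33 and 216 of 235 calls with the fit without it. Of the named genes it ended the calls of Slc16a3 for hypoxia without lactate and of Ldha and Cx3cr1 for hypoxia with lactate. Depth limits low genes, and hypoxia-lactate 3 limits all fits that hold it.

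Counts higher and lower were, by DESeq2, 117 and 36 for hypoxia without lactate, 6 and 4 for lactate in normoxia, 51 and 61 for lactate in hypoxia, 283 and 154 for hypoxia with lactate, 861 and 589 for both together, and 1 and 0 for the interaction. Without both outlying libraries they were 151 and 37, 2 and 1, 5 and 6, 236 and 144, and 481 and 431 in that order, with quality weights 316 and 209, 5 and 6, 11 and 5, 485 and 252, 586 and 492, and 1 and 1, and with the block without hypoxia-lactate 3 372 and 395, 14 and 29, 8 and 8, 161 and 100, and 1015 and 1101. Fitting only the groups compared, with fewer libraries, gave 50 higher and 9 lower for hypoxia without lactate, 3 and 0 for hypoxia with lactate, and 6 and 0 for both together. For hypoxia without lactate 1 was lower with upper-quartile factors and with no filter, for lactate in normoxia 1 was higher with no filter, and for hypoxia with lactate 2 were lower with the 5 CPM filter.

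Leaving out each library in turn gave 7 to 186 higher and 0 to 84 lower for hypoxia without lactate, 0 to 4 and 0 to 1 for lactate in normoxia, 0 to 3 and 0 to 3 for lactate in hypoxia, 3 to 98 and 0 to 32 for hypoxia with lactate, 49 to 543 and 15 to 492 for both together, and 0 for the interaction. The correlation of hypoxia effects ranged from 0.135 to 0.388, that of lactate effects from -0.047 to 0.206 (-0.014 without hypoxia-lactate 1, -0.028 without hypoxia-lactate 2, -0.047 without normoxia-NaCl 2) and the overlap of hypoxia and lactate effects against the shared control from 0.488 to 0.734; with the 5 CPM filter the first 2 were 0.343 and 0.112. Upper-quartile factors moved the median of all genes to -0.148 for lactate in hypoxia, -0.164 for hypoxia with lactate and -0.163 for the interaction, and limma-voom to -0.118, -0.129 and -0.126, with -0.12 for both together; with no filter it was -0.135 for the interaction.

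Sign changes, none of a called value, were in the interaction Mrc1 at 0.011 with quality weights; Vegfa at -0.032 without both outlying libraries, -0.195 with the block without hypoxia-lactate 3 and -0.189 without hypoxia-lactate 3 (to 0.706 over libraries left out); and Nos2 at -1.075 by limma-voom, -0.807 with quality weights, -0.802 without hypoxia-lactate 1 and -4.041 without normoxia-NaCl 2 (to 1.098). Slc2a1 was at -0.186 with upper-quartile factors, -0.057 with the 5 CPM filter, -0.008 with the block, -0.295 without both outlying libraries, -0.132 with quality weights and -0.269 with the block without hypoxia-lactate 3. It was at -0.016, -0.114, -0.291, -0.03 and -0.11 without hypoxia-NaCl 1, hypoxia-NaCl 2, hypoxia-lactate 3, normoxia-lactate 1 and normoxia-lactate 3 (to 0.205). Hif1a for hypoxia without lactate was at -0.057 without hypoxia-NaCl 2 and -0.052 without normoxia-NaCl 3 (to 0.098).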

Other observations

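The tests of sex-linked transcripts and of other splits of the libraries were chosen only after the results were seen, and the genes in the next paragraph were chosen after their values were seen.

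Without hypoxia-lactate 3, lactate in normoxia raised the HSP70 genes Hspa1a (log2 1.99 ± 0.24), Hspa1b (2.21 ± 0.30) and Hspa1l (1.63 ± 0.20) and the interferon-induced transmembrane gene Ifitm6 (1.79 ± 0.21), and lowered Cd33 (-1.49 ± 0.20), with edgeR BH-adjusted p of 0.00841 for Hspa1a, Hspa1l and Ifitm6 and 0.0142 for Hspa1b and Cd33. Over all alternatives these ranged from 0.000762 to 1 for Hspa1a, 2.36e-06 to 1 for Hspa1b, 3.03e-09 to 1 for Hspa1l, 0.00335 to 1 for Ifitm6 and 4.67e-08 to 1 for Cd33. In hypoxia Cd33 fell with lactate too (-1.53 ± 0.23, edgeR BH-adjusted p = 0.0465; 1.27e-07 to 0.829 over its alternatives). For both conditions together without that library the complement genes C1qa (-2.49 ± 0.48), C1qb (-1.97 ± 0.36) and C1qc (-1.68 ± 0.38) and the phagocytic receptor Mertk (-2.08 ± 0.32) fell, with edgeR BH-adjusted p of 0.0102, 0.00797, 0.0208 and 0.00314 against 0.521, 0.202, 0.33 and 0.0693 with all libraries.

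The effects of low oxygen and of lactate, each against normoxia-NaCl, resembled each other, which the shared control libraries may explain at least in part. The lowest ratio of the observed covariance to the highest of 20 simulated ones was 0.884, without both outlying libraries; it was 0.887 with all libraries and 1.71 without hypoxia-lactate 3. The covariance minus the simulated mean was -0.00962, 0.0622 and -0.00599 with all libraries, without hypoxia-lactate 3 and without both. Without hypoxia-lactate 3 the calls shared 4 higher and 1 lower genes, where the simulations shared 0 and independent lists would share 0.0493 and 0.00557. The simulated groups were unchanged and independent lists leave out the shared controls. Neither allows for effects and shared controls at once, so the shared calls do not weigh against shared controls. The correlation of the main effects of low oxygen and lactate over all 4 groups was 0.627, 0.504 and 0.455 in these 3 fits, against a highest simulated value of 0.0505, 0.167 and 0.24, which goes against shared controls as the whole cause. It does not settle this, since normoxia-NaCl and hypoxia-lactate, the groups of the outlying libraries, enter both main effects with the same sign and the simulations gave every library of a gene the same spread. With 3 controls no split leaves 2 libraries on each side, so part of any excess may come from the controls.

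Every library held both Xist and Y-linked transcripts. Scaled to the library total without TMM factors, Xist was at 40.1 CPM in hypoxia-lactate 3 and 49.5 in normoxia-NaCl 1, against 135 to 236 in the others, and Y-linked genes summed to 30.7 to 72.2 CPM. Cells of both sexes in every library could give this, but the quotient of Y-linked to Xist counts differed 6.51-fold between libraries, which lies between the bounds set for and against. That range rests on hypoxia-lactate 3, with a quotient of 1.74. Normoxia-NaCl 1 was next at 0.621, and the others lay at 0.268 to 0.428.

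Splits of 6 libraries into 3 and 3 number 10, too few for a share under 0.05. The real counts of changed genes were 41 for hypoxia without lactate, 33 for hypoxia with lactate and 235 for both together, each reached by 1 of the 10 splits, with 0 as the highest other, and 0 for lactate in normoxia and in hypoxia, which all 10 splits reach whatever they hold. For hypoxia without lactate the splits that part all 3 numbered pairs, other than the real one, also gave 0. For the interaction the real count was 0 as well, reached by 60 of 60 drawn splits, so for these 3 comparisons the splits say nothing about chance.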
